A study of Mus musculus with 12 samples.

How the data were processed

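RNA was measured in pools of fluorescent retinal ganglion cells picked by hand from mouse retina. There were 12 libraries in 4 groups of 3. Opn4 cells came from Opn4CreERT/+;R26-tdTomato mice, in which tamoxifen turns on a red reporter in melanopsin-expressing, intrinsically photosensitive retinal ganglion cells (ipRGCs). HB9 cells came from HB9:GFP mice, in which a green reporter marks ON-OFF direction-selective ganglion cells (ooDSGCs). Per the labels, tamoxifen was injected at 0.124 mg per g for 5 days from postnatal day 21, optic nerve crush or sham surgery followed at postnatal day 42, and retinas were taken 3 days later. Tissue was digested with papain at 17 U per ml for 30 minutes at 37 °C, and cells were picked within 2 hours of euthanasia. Each animal gave 10 cells, and 3 such pools made 1 sample of 30 cells. The RNA was extracted with a nanoscale kit, amplified as cDNA and sequenced on an Illumina instrument. Mice of both lines received tamoxifen. Cre recombinase belongs to the Opn4 line alone, as does the red reporter, so they cannot be separated from the cell class, while the crush effect is measured within each line.

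The deposited table holds 1 RPKM value (reads scaled by gene length and by the total of the library) per gene and library, made by the authors, for 38887 Ensembl genes on 21 chromosomes. The submitters' processing notes name TopHat2 2.0.11, Bowtie, edgeR 3.14.0 and genome build mm10. They do not state which step used edgeR, how reads were counted or which annotation gave the gene lengths. Mitochondrial transcripts are not analysed here. The RPKM of short genes times their length fell on whole multiples of 1 step per library, with 100% of these values within 0.01 read of a whole number, and the step gave the total by which each library had been scaled. Those totals ranged from 15104446 reads in Opn4 sham replicate 2 to 28195798 reads in HB9 crush replicate 2. The same arithmetic gave whole reads and a length for each of the 28168 genes above 0. On 1000 simulated genes it returned the right length for 100%. Recovered reads in the listed genes summed to between 35000431 and 68410758 per library, which is 226.7% to 244.2% of the scaling totals, so that reads were counted more than once or the total was not of the same reads. The files do not say which, and the recovered reads are used below only for floors and in 1 alternative. Pseudogenes held 7.55% to 10.5% of the recovered reads. Gene IDs and coordinates are those of the deposited table. Of its IDs, 96.6% were found in the GENCODE annotation of the same build, and 99.5% of those lay within 100000 bp of the listed position. Coordinates were the same for 70.3%, and 51.6% of 8380 compared recovered lengths equalled the summed exons of that annotation.

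Values were tested as log2(RPKM + 1) for the 18269 genes with an RPKM of at least 1 in at least 3 of the 12 libraries. All 12 libraries entered 1 linear model with 4 group means (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with an intensity trend). The 6 comparisons were the crush effect in Opn4 cells, the crush effect in HB9 cells, their mean, their difference (Opn4 minus HB9, an interaction contrast), and the difference between classes (Opn4 minus HB9) after sham and after crush. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and an adjusted p under 0.05 counted as past the threshold. Errors of log2 changes are the limma standard errors with n = 3 libraries per group, and errors of RPKM are standard deviations. Intervals of depth cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A group with all libraries at 0 was given a floor of 3 reads over the group. Folds against it, given as "at least", are lower bounds for the counting error of reads alone. They do not cover RNA lost before amplification, so they are not bounds on expression in the cells. Elsewhere, log2 changes of genes near 0 RPKM are damped by the pseudocount of 1.

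Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, for each list with at least 5 tested members, and adjusted over the lists of a comparison. The test was repeated with a correlation estimated for each list. Of 34 lists, 31 were tested; the vascular and pericyte list had 3 tested members, the erythrocyte list 2, and the mitochondrially encoded list 0. Lists for other retinal cells covered rods, cones, bipolar cells, amacrine cells, Muller glia and astrocytes, and microglia and macrophages. Named genes were taken by a rule. It named the following genes whatever they showed (Opn4, Eomes, Cartpt, Mnx1, Col25a1 and Cdh6 for class, Rbpms, Slc17a6, Nefl and Thy1 for ganglion cells, and Thbs1, Sox11, Atf3, Jun, Gap43, Sprr1a and Ecel1 for injury). For each comparison it added the 10 highest and 10 lowest log2 changes past the threshold among genes whose libraries did not overlap between the groups and whose mean reached 5 RPKM in the higher group. For the mean effect the libraries could not overlap within either class, and for the difference the crush effects had to oppose each other or differ by at least 1 log2 unit. Predicted gene models and pseudogenes were left out of this rule. It also added up to 4 members of each list by p-value. Some genes that the rule took are not reported here. The groups, comparisons, lists and naming rule were fixed before the data were examined.

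The alternatives chosen in advance changed the threshold to 0.1, the pseudocount to 0.1, the filter (none, or an RPKM of 5), the scaling (quantile normalization or median-ratio rescaling), the weights of the libraries (limma arrayWeights), the libraries in the fit, and the correlation of the list test, took the replicate number as a block, and left out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, the mean rod value as a covariate, a fit on named protein-coding genes alone, and a fit without the 2 Opn4 libraries that stood apart. Over 18 pairs with the same replicate number in different groups, residual correlations ran from -0.022 to 0.081. They ran from -0.080 to 0.070 over 36 pairs with other numbers, and 5 of 12 libraries correlated best with a library of their own number. The mean rod value was highest in replicate 1 of each group (6.43, 6.88, 5.15 and 5.09), so an effect shared by replicate number is not excluded.

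The procedure was tested on simulated data, in which libraries of unchanged groups were drawn with the spread of each class and changes were added to 50 genes per size. Changes of 2, 4, 8 and 16 fold were called in the right direction for 18%, 72%, 80% and 86% in Opn4 cells and for 14%, 64%, 78% and 94% in HB9 cells. Of 18050 genes left unchanged, some missed the RPKM filter, and 17729 and 17726 simulated genes in all were tested. Among the unchanged genes, 68 were called in Opn4 cells and 10 in HB9 cells. The 68 were a larger share of the simulated Opn4 calls than the threshold implies. A shifted cholesterol synthesis list passed in both classes, and 0 of 30 other lists did. Noise was drawn for each gene on its own, so members of a list were not correlated. The simulation therefore cannot tell how often lists with correlated members pass falsely. Read recovery and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.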

Results

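RNA was sequenced from 12 hand-picked pools of 30 retinal ganglion cells each, in a study that looked for regulators of axon regeneration after optic nerve injury. The pools fell into 4 groups of 3: intrinsically photosensitive cells (Opn4 cells) and ON-OFF direction-selective cells (HB9 cells), each 3 days after sham surgery or optic nerve crush. The deposited values are RPKM, and the mouse genome build is mm10. The Opn4 sham libraries had been scaled to 22905890, 15104446 and 21500526 reads, and the Opn4 crush libraries to 17328143, 18121564 and 21159095 reads. Scaling totals of the HB9 libraries were 22447562, 24637164 and 19874394 reads after sham and 23254935, 28195798 and 26467045 reads after crush. Each library held between 15021 and 16514 genes at an RPKM of 1 or more. Below, RPKM is given as mean ± SD with n = 3 libraries per group, and log2 changes as estimate ± SE from the limma fit of all 12 libraries.

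Cell class was the main axis of variation: the leading principal component, with 31.4% of the variance, set the 6 Opn4 libraries apart from the 6 HB9 libraries. Libraries of Opn4 cells also differed more among themselves, with a median within-group SD of 0.47 after sham and 0.51 after crush on the log2 scale, against 0.33 and 0.34 for HB9 cells. Opn4 sham replicate 1 and Opn4 crush replicate 1 lay far from the others on the third component, at 83.8 and -61.9. Transcripts of rods, the most common photoreceptors, were present in every library. The mean log2 value of the rod genes was 5.76 ± 0.71 and 6.14 ± 0.67 in Opn4 cells after sham and crush, and 4.31 ± 0.76 and 4.77 ± 0.28 in HB9 cells (SD, n = 3).

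The uninjured classes were compared to see how these ganglion cell types differ before any lesion. Melanopsin (Opn4; ENSMUSG00000021799, chromosome 14, 34590618 to 34600142), the photopigment that defines ipRGCs, was at 1576 ± 281 RPKM in Opn4 cells and 8.42 ± 10.5 RPKM in HB9 cells, a log2 difference of 8.22 ± 0.90 (adjusted p = 7.05e-05). Eomes, a transcription factor that maintains ipRGCs, differed by 7.73 ± 0.32 (adjusted p = 5.23e-08), and Cd24a, a surface glycoprotein, by 8.93 ± 0.52 (adjusted p = 6.65e-07). HB9 cells held more Mnx1 (ENSMUSG00000001566, chromosome 5, 29473038 to 29478519), the gene whose promoter drives the HB9 reporter, at 32.2 ± 10.5 against 0.0481 ± 0.0833 RPKM, with a log2 difference of -4.94 ± 0.43 (adjusted p = 1.16e-05). They also held more of the peptide precursor Cartpt, an ooDSGC marker, at 5383 ± 608 against 149 ± 23.9 RPKM (-5.17 ± 0.45, adjusted p = 1.30e-05). The nicotinic receptor subunit Chrna6 differed by -7.67 ± 0.57 (adjusted p = 3.89e-06) and the calcium buffer Pvalb by -6.99 ± 0.74 (adjusted p = 5.57e-05), both lower in Opn4 cells. Crhbp, which binds corticotropin-releasing hormone, was lower as well, at -7.88 ± 0.67 (adjusted p = 1.01e-05). Of 18269 genes, 1064 were higher and 1084 lower in Opn4 cells, and 485 and 364 of these differed by more than 4-fold. Neuromedin B (Nmb, 8.13), Gldn (7.45), Zcchc12 (7.26), the cation channel Trpc7 (7.0), the G protein subunit Gna14 (6.9), Prkcd (6.57) and the adhesion molecule Chl1 (6.54) completed the 10 highest. The lowest included the transcription factor Tfap2d (-6.98), Chrnb3 (-6.98), the protease Mmp9 (-6.62), the guidance ligand Sema3e (-6.25), Rbpms2 (-6.16), Anxa2 (-5.8) and Pcdh7 (-5.77). Of the markers named in advance, Cdh6 differed by -4.97 ± 0.61 (adjusted p = 0.000198) and Col25a1 by -3.87 ± 0.83 (adjusted p = 0.00835), whose call ended with a pseudocount of 0.1 (adjusted p = 0.0642) and with the rod covariate (0.31). The count fell to 1348 without HB9 sham replicate 2, to 1401 without replicate 3, and to 784 with the mean rod value as a covariate.

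Marker lists of each class separated the uninjured cells. Of 12 ipRGC markers, 11 were higher in Opn4 cells (also 11 adjusted over the list alone). The median was 5.78 (list adjusted p = 7.04e-22, and 0.00226 with an estimated correlation). Of 11 ooDSGC markers, 7 were lower (9 adjusted over the list alone). The list median was -3.2 (adjusted p = 1.01e-07, and 0.00739 with an estimated correlation). Genes shared by most ganglion cells were mostly lower in Opn4 cells, 12 of 20 against 1 higher (12 and 2 adjusted over the list alone). The median was -1.33 (adjusted p = 2.79e-08, and 0.00992 with an estimated correlation). Among them the vesicular glutamate transporter Slc17a6 was at 208 ± 8.56 and 862 ± 139 RPKM (-2.03) and the transcription factor Pou4f3 differed by -4.33, while Rbpms, a general ganglion cell marker, was at -0.29 (adjusted p = 0.311). The neurofilament Nefl differed by -1.47 ± 0.20 (adjusted p = 0.000347), and Thy1 by -0.92 ± 0.22 (adjusted p = 0.0149), a call that ended without HB9 sham 1 or 2 (adjusted p up to 0.0694). Synaptic release genes were lower (12 of 24, 1 higher; 15 and 1 adjusted over the list alone), with the fusion regulator Cplx1 at -3.04 and Vamp1 at -4.49. Their median was -0.66 (adjusted p = 9.71e-09, and 0.00739 with an estimated correlation). So were voltage-gated channels (15 of 27, 2 higher; 16 and 4 adjusted over the list alone), among them the sodium channel subunit Scn1a (-2.8). The median was -1.17 (adjusted p = 9.59e-07, and 0.00992 with an estimated correlation). Glycolysis enzymes were lower in 14 of 20 (16 adjusted over the list alone), with Ldhb at -2.25 and Pgam1 at -1.47. The median was -0.84 (adjusted p = 3.55e-14, and 0.013 with an estimated correlation). Thrombospondins and their receptors were higher in 6 of 14 and lower in 1 (8 and 1 adjusted over the list alone), led by the syndecan Sdc2 (3.54) and thrombospondin 1 (Thbs1, 2.92). The list median was 1.29 (adjusted p = 0.000127, and 0.0128 with an estimated correlation).

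Further lists differed between the uninjured classes with the preset correlation alone. Higher in Opn4 cells were cholesterol synthesis (6 of 19 genes, 8 adjusted over the list alone, median 0.62, adjusted p = 0.0716 with an estimated correlation) and ribosomal proteins (9 of 83, also 9 adjusted over the list alone, median 0.45, 0.441). Regeneration-associated genes were higher in 7 and lower in 3 of 27 (11 and 3 adjusted over the list alone, median 0.23, adjusted p = 0.072 with an estimated correlation). Tubulin and stathmin genes were higher in 3 and lower in 2 of 25 (8 and 3 adjusted over the list alone, median 0.38, 0.475). Lower were nuclear genes of oxidative phosphorylation (6 of 34, 16 adjusted over the list alone, median -0.42, 0.441), transmitter receptors (9 of 26, 2 higher, 11 and 3 adjusted over the list alone, median -0.62, 0.238) and markers of other ganglion cell types (3 of 9, also 3 adjusted over the list alone, median -1.44, 0.0716). Rod markers moved with class as well: 1 of 15 passed alone, Cnga1 of the rod channel at 2.9 ± 0.67 (adjusted p = 0.0138), but 9 were higher adjusted over the list alone (median 1.4, list adjusted p = 3.45e-05, and 0.395 with an estimated correlation). The call of Cnga1 ended without Opn4 sham 1 or HB9 sham 2 or 3 (adjusted p up to 0.0613). Markers of cones (median 0.79, adjusted p = 0.474), amacrine cells (0.24, 0.219), bipolar cells (0.23, 0.961, with a mean of -0.15), Muller glia and astrocytes (0.40, 0.26) and microglia (-0.12, 0.959) did not pass. The list calls ended for other ganglion cell types without Opn4 sham 3 (adjusted p = 0.0543), for regeneration-associated genes with limma voom on recovered reads (adjusted p = 0.0626), and for tubulins with the stricter filter (0.055).

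**Figure D1:**
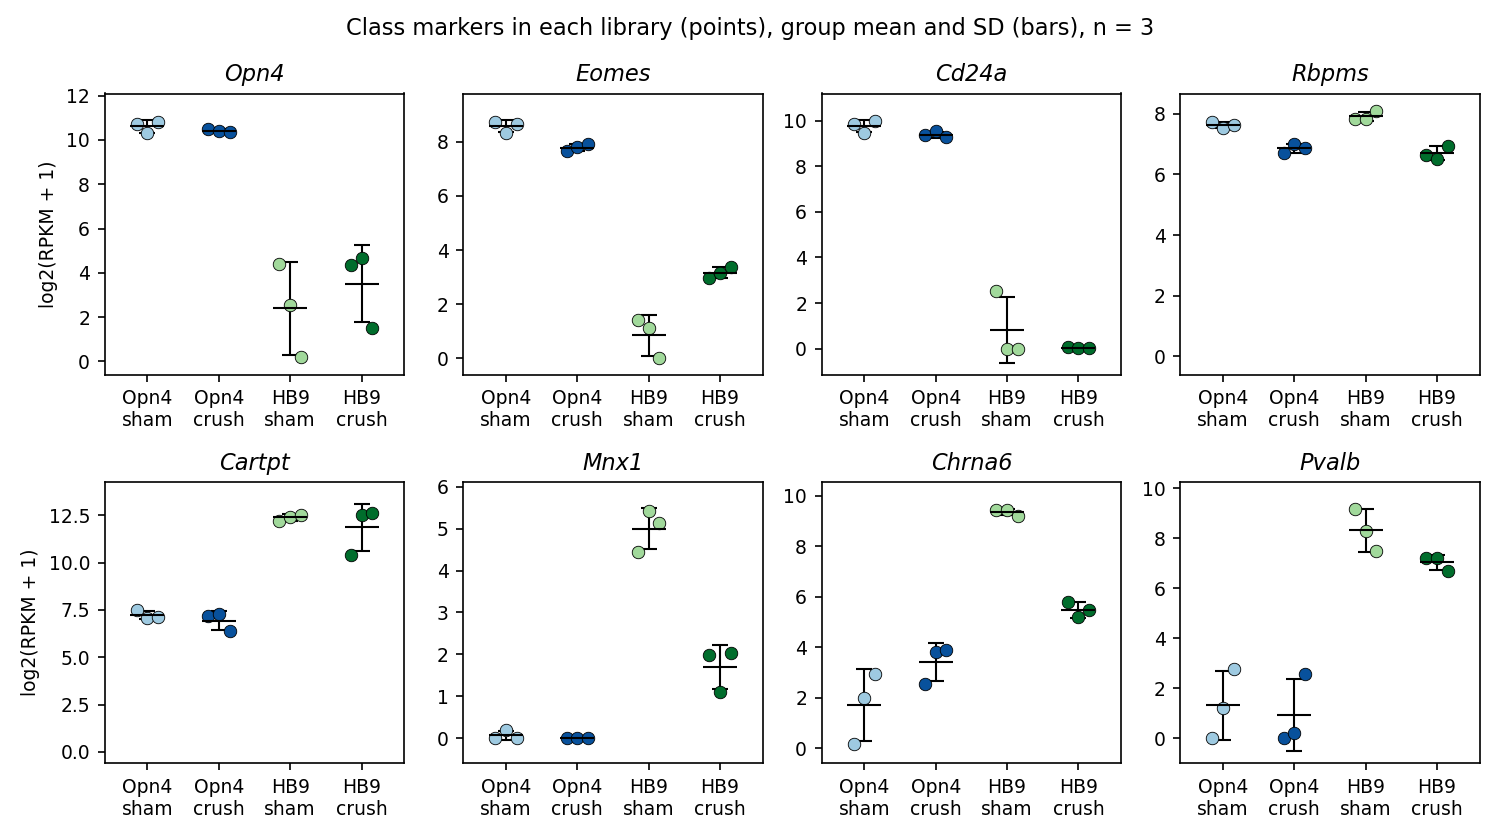
Level of 8 class markers, as log2(RPKM + 1) on the vertical axis, in each library (points) of the 4 groups on the horizontal axis; bars give the group mean and SD (n = 3). Opn4, Eomes and Cd24a are high in the Opn4 groups, Cartpt, Mnx1, Chrna6 and Pvalb in the HB9 groups, and after crush Mnx1 drops to 2.38 RPKM and Chrna6 to 44.3 RPKM in HB9 cells.

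The crush effect in Opn4 cells was measured to see how ipRGCs respond to axon injury. Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191183340), a stress-induced factor, went from 0.0824 ± 0.105 to 59.2 ± 17.4 RPKM (log2 change 5.76 ± 0.31, adjusted p = 1.32e-06). Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), the target of JNK signalling, went from 11 ± 0.242 to 246 ± 42.2 RPKM (4.34 ± 0.21, adjusted p = 6.34e-07). Thrombospondin 1 (Thbs1; ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), a secreted matrix protein, rose from 8.63 ± 3.09 to 192 ± 26.9 RPKM (4.36 ± 0.41, adjusted p = 0.00027). Ecel1, a peptidase induced by nerve injury, rose by 5.58 ± 0.46 (adjusted p = 9.24e-05), though not with limma voom on recovered reads (adjusted p = 0.175). The cytokine receptor Tnfrsf12a (3.78 ± 0.33, adjusted p = 0.000168) and the secreted neuropeptide precursor Vgf (3.82 ± 0.55, adjusted p = 0.00474) rose too. In all, 126 genes rose and 77 fell, 60 and 42 of them by more than 4-fold, and 2619 had an unadjusted p under 0.05. The balance was not firm, with 111 up and 113 down without Opn4 crush 2, and 63 and 24 with weighted libraries. The kainate receptor subunit Grik1 (4.26) and the DNA-binding protein Arid5a (3.98) rose, but not with voom (adjusted p = 0.0945 and 0.0978). Grik1 is also on the list of bipolar markers, which had a median of 0.38 in Opn4 cells and did not pass. Stmn4, a stathmin, rose by 4.16, a call that ended without Opn4 crush 1, 2 or 3 (adjusted p up to 0.0597). A pair of microRNA genes was among the 10 highest. Mir147, which lies in the likewise induced AA467197, was at least 40.4-fold higher, and Mir5117, which lies in Gas5, at least 31-fold, a call lost without the libraries that stood apart (adjusted p = 0.0528). Reads of these microRNA genes were not told apart from reads of their host transcripts, so the values do not show a rise of the microRNAs.

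After crush in Opn4 cells the chemokine Ccl17 fell from 17.4 ± 9.89 to 0 RPKM, at least 168-fold lower (-4.0 ± 0.48, adjusted p = 0.00161). Mad2l1bp, a silencer of the mitotic checkpoint, fell by 3.61 ± 0.49 (adjusted p = 0.00343), and Exo5 (-3.16), Zfp90 (-3.14) and Ccdc65 (-3.09) fell as well, Zfp90 not with voom (adjusted p = 0.0745). The other 5 of the 10 lowest were Mfsd3 (-3.55, at least 548-fold lower), Fdxacb1 (-3.3), Dctpp1 (-3.29), Ap5z1 (-3.24) and G0s2 (-3.2). The call of Mfsd3 ended without Opn4 sham 1 or 2 or Opn4 crush 1, 2 or 3 (adjusted p up to 0.101), and that of Fdxacb1 without Opn4 sham 1 or 3 or Opn4 crush 1 or 2 (adjusted p up to 0.0862). Dctpp1 lost its call without Opn4 sham 1 or 2 or Opn4 crush 1, 2 or 3 (adjusted p up to 0.11), and Ap5z1 without Opn4 sham 1 or 3 or Opn4 crush 1 or 3 (adjusted p up to 0.0868). For G0s2 it ended without Opn4 sham 1 or 3 or Opn4 crush 1, 2 or 3 (adjusted p up to 0.0876). Genes fixed in advance that stayed short of the threshold were the growth cone protein Gap43 at 0.29 (adjusted p = 0.499), Sox11 at 0.74 (adjusted p = 0.645), Sprr1a at -0.20 (adjusted p = 0.933), Opn4 at -0.20 (adjusted p = 0.954) and Eomes at -0.79 (adjusted p = 0.29). Also short of it were Slc17a6 at 0.02 (adjusted p = 0.989), Nefl at -0.18 (adjusted p = 0.725) and Thy1 at 0.31 (adjusted p = 0.555). Fitted on the 6 Opn4 libraries alone, the count was 13 genes (7 higher, 6 lower), and it was 87 with weighted libraries. Replicate spread in Opn4 cells exceeds that in HB9 cells, and the 12-library fit pools both. In simulations with these spreads, 18050 genes were left unchanged, and some of them missed the RPKM filter. Of the unchanged genes, 68 were called in Opn4 cells and 10 in HB9 cells. Of 50 genes changed per size in Opn4 cells, 18%, 72%, 80% and 86% were called at 2, 4, 8 and 16 fold. The 68 were thus a larger share of the simulated Opn4 calls than the threshold implies. The Opn4 crush calls of the 12-library fit may likewise hold more false ones.

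By list, regeneration-associated genes, those induced in neurons that regrow axons, rose in 7 of 27 and fell in 1 in Opn4 cells (12 and 1 adjusted over the list alone). The median was 0.67 (adjusted p = 7.73e-13, and 0.00122 with an estimated correlation). The unfolded protein and integrated stress response rose in 5 of 27 (10 rose and 1 fell adjusted over the list alone). Their median was 0.45 (adjusted p = 1.08e-06, and 0.0253 with an estimated correlation). Its members included the amino acid transporter Slc7a5 (1.82) and the pro-apoptotic factor Ddit3 (1.92), the latter not without Opn4 sham 3 (adjusted p = 0.0501). Cholesterol synthesis fell in 4 of 19 enzymes and regulators (11 adjusted over the list alone), with Fdps at -2.01 ± 0.24 (adjusted p = 0.00161) and Hmgcs1 at -1.08 ± 0.17 (adjusted p = 0.0098). The median was -0.90 (adjusted p = 3.83e-09, and 0.0278 with an estimated correlation). Tubulins and stathmins, the building blocks and regulators of microtubules, fell in 6 of 25 and rose in 1 (13 and 1 adjusted over the list alone), with Tubb4b at -1.88 ± 0.19 (adjusted p = 0.00055). The median was -0.65 (adjusted p = 3.83e-09, but 0.137 with an estimated correlation). Immediate early genes rose in 3 of 19 (6 adjusted over the list alone), Jund (1.61) and the phosphatase Dusp1 (2.05) among them. The list median was 0.90 (adjusted p = 9.50e-07, but 0.217 with an estimated correlation). DLK-JNK and apoptosis genes rose in 4 of 24 (6 rose and 3 fell adjusted over the list alone), a call that ended without Opn4 sham 1 or Opn4 crush 3 (adjusted p up to 0.0763). The median was 0.18 (adjusted p = 0.011, but 0.289 with an estimated correlation). Interferon-stimulated genes rose in 1 of 15 (3 rose and 1 fell adjusted over the list alone), not without Opn4 crush 2 (adjusted p = 0.0996). Their median was 0.96 (adjusted p = 0.00371, but 0.395 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.16 with no gene past the threshold (adjusted p = 0.011, but 0.597 with an estimated correlation), not without Opn4 sham 1 or Opn4 crush 1 (adjusted p up to 0.283). Ganglion cell genes did not pass as a list (median -0.17, mean 0.03, adjusted p = 0.649). Of their members Rbpms fell by 0.78 ± 0.16 (adjusted p = 0.0409), a call that ended without Opn4 sham 1, 2 or 3 or Opn4 crush 1 or 3 (adjusted p up to 0.101). ipRGC markers did not pass either (-0.38, 0.117), nor did rod markers (0.43, 0.13).

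The crush effect in HB9 cells was measured to see how ooDSGCs respond to the same injury. Ecel1 (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521) rose from 0.0853 ± 0.0298 to 701 ± 300 RPKM (9.26 ± 0.46, adjusted p = 3.84e-07) and Atf3 from 0.0868 ± 0.0581 to 540 ± 105 RPKM (8.94 ± 0.31, adjusted p = 1.08e-08). Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), a cornified envelope protein induced in regenerating neurons, rose from 0.166 ± 0.287 to 729 ± 569 RPKM (8.77 ± 0.70, adjusted p = 1.43e-05). Peptides of the corticotropin-releasing family rose too. Crh went from 0.0445 ± 0.0149 to 305 ± 230 RPKM (7.61 ± 0.71, adjusted p = 4.67e-05). Urocortin (Ucn) went from 0 to 102 ± 87.2 RPKM, at least 1144-fold higher (6.23 ± 0.60, adjusted p = 5.27e-05). The calls of Sprr1a and Crh ended with voom (adjusted p = 0.127 and 0.117). The cell-cycle inhibitor Cdkn1a rose by 6.19 ± 0.35 (adjusted p = 1.25e-06), Jun by 3.26 ± 0.21 (adjusted p = 3.63e-06) and Gap43 by 1.0 ± 0.18 (adjusted p = 0.00473). Mnx1 fell from 32.2 ± 10.5 to 2.38 ± 1.09 RPKM (-3.3 ± 0.43, adjusted p = 0.000471) and Chrna6 from 658 ± 56.1 to 44.3 ± 9.87 RPKM (-3.88 ± 0.57, adjusted p = 0.00113). The count was 702 genes up and 470 down, with 268 and 91 beyond 4-fold, and 3445 had an unadjusted p under 0.05. The median over all genes was 0.11, and quantile normalization shifted it by -0.13 and left 600 genes up and 605 down, against 611 and 671 with median-ratio rescaling. The respiratory chain subunit Cox6a2 (7.26), the lysosomal protein Cd68 (6.69), the glycoprotein Gpnmb (6.44) and the retinoic acid carrier Crabp2 (6.26) were among the 10 highest. The peptide cholecystokinin (Cck, -4.89), the calcium sensor Scgn (-4.74, at least 1172-fold lower), the sodium pump regulator Fxyd7 (-3.98), Lect1 (-3.73), Kctd4 (-3.59), Shroom2 (-3.54) and Rasgrp2 (-3.37) were among the 10 lowest. Scgn is also on the list of bipolar markers, which fell with the preset correlation alone. Fixed genes without a call were Thbs1 at -0.29 (adjusted p = 0.787), Sox11 at 1.99 (adjusted p = 0.0964), Opn4 at 1.12 (adjusted p = 0.588), Cartpt at -0.53 (adjusted p = 0.619), Cdh6 at -1.49 (adjusted p = 0.201) and Col25a1 at -0.91 (adjusted p = 0.645). Without HB9 sham replicate 1, 2 or 3 the count was 777, 681 or 645, and without HB9 crush replicate 1, 2 or 3 it was 656, 758 or 684. It was 3025 with weighted libraries and 1939 in a fit of the 6 HB9 libraries alone.

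Gene lists were tested for the crush effect in HB9 cells as well. The unfolded protein and integrated stress response rose in 20 of 27 genes (21 adjusted over the list alone). The median was 2.11 (adjusted p = 1.89e-22, and 0.000287 with an estimated correlation). Slc7a5 rose by 4.03, its partner subunit Slc3a2 by 3.32, asparagine synthetase (Asns) by 2.11 and the tryptophan tRNA synthetase Wars by 1.6. Regeneration-associated genes rose in 18 of 27 and fell in 1 (22 and 2 adjusted over the list alone). The median was 2.45 (adjusted p = 6.69e-22, and 0.000177 with an estimated correlation). Cholesterol synthesis fell in 10 of 19 (16 adjusted over the list alone), with Idi1 at -2.17 ± 0.35 (adjusted p = 0.00216). The list median was -1.13 (adjusted p = 4.45e-13, and 0.00547 with an estimated correlation). Ganglion cell genes fell in 8 of 20 (10 adjusted over the list alone). The median was -0.83 (adjusted p = 6.39e-11, and 0.00466 with an estimated correlation). Rbpms fell by 1.22 ± 0.16 (adjusted p = 0.000599), while Slc17a6 was at 0.02 (adjusted p = 0.977), Nefl at -0.70 (adjusted p = 0.0548) and Thy1 at -0.40 (adjusted p = 0.369). Voltage-gated channels fell in 8 of 27 (12 fell and 1 rose adjusted over the list alone), Kcnab2 at -1.6 and Scn3b at -2.04 among them. Their median was -0.71 (adjusted p = 6.43e-09, and 0.00466 with an estimated correlation). Synaptic release genes fell in 4 of 24 and rose in 1 (7 and 1 adjusted over the list alone). The median was -0.39 (adjusted p = 5.05e-05, and 0.0211 with an estimated correlation). The vesicle GTPase Rab3a was at -1.27. ON-OFF direction-selective cell markers fell in 2 of 11 (3 adjusted over the list alone). The median was -1.25 (adjusted p = 7.64e-05, and 0.0207 with an estimated correlation). The 2 genes were Mnx1, and Satb1 at -1.42 ± 0.33 (adjusted p = 0.0215), whose call ended without HB9 sham 1, 2 or 3 or HB9 crush 1 or 2 (adjusted p up to 0.0979).

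Other HB9 lists passed with the preset correlation but not with an estimated correlation. Tubulins and stathmins fell in 10 of 25 and rose in 2 (13 and 3 adjusted over the list alone). The list median was -0.66 (adjusted p = 0.0988 with an estimated correlation). Glycolysis fell in 8 of 20 (12 fell and 3 rose adjusted over the list alone; median -0.46, 0.10), with Ldha at -1.12. Proteasome and ubiquitin genes rose in 4 of 28 (5 adjusted over the list alone; median 0.27, 0.276), the autophagy receptor Sqstm1 at 1.53. Ribosomal proteins rose in 4 of 83 (also 4 adjusted over the list alone; median 0.37, 0.417). DLK-JNK and apoptosis genes rose in 5 and fell in 1 of 24 (6 and 1 adjusted over the list alone; median 0.38, 0.198), the BH3-only proteins Hrk (3.74) and Bbc3 (3.35) among them. Immediate early genes rose in 5 and fell in 1 of 19 (7 and 1 adjusted over the list alone; median 0.66, 0.276). Interferon-stimulated genes rose in 2 of 15 (4 adjusted over the list alone; median 1.09, 0.276), the class I light chain B2m at 4.1. Transmitter receptors (median -0.48, 0.239), receptors of axon growth inhibitors (-0.34, 0.246) and nuclear oxidative phosphorylation genes (-0.18, 0.434) fell, with 1, 1 and 0 genes past the threshold, also adjusted over the list alone. Beside these, ipRGC markers rose in 2 of 12 (4 adjusted over the list alone; median 0.53, 0.20). The neuropeptide gene Adcyap1 rose by 2.77 ± 0.23 (adjusted p = 2.07e-05) and Eomes by 2.32 ± 0.32 (adjusted p = 0.000837), the latter not with voom (adjusted p = 0.0673). Adcyap1 is also on the list of regeneration-associated genes, so it counts in the rise of both lists. Microglia and macrophage markers rose in 2 of 5 (also 2 adjusted over the list alone; median 0.45, 0.165). Cd68 was 1 of them, while Csf1r was at 0.45 (adjusted p = 0.734) and Lyz2 at -0.33 (adjusted p = 0.885). Bipolar markers fell in 1 of 12, which was Scgn (also 1 adjusted over the list alone; median -0.98, 0.276). Preset list calls ended without HB9 crush 2 for ipRGC, microglia, bipolar and interferon lists, for receptors of axon growth inhibitors without HB9 sham 3 or HB9 crush 2 (adjusted p up to 0.13), and for oxidative phosphorylation without HB9 sham 1 or HB9 crush 3 (adjusted p up to 0.122). Without HB9 crush 2 the adjusted p was 0.0815 for ipRGC markers, 0.127 for microglia and macrophage markers, 0.112 for bipolar markers and 0.189 for interferon-stimulated genes.

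**Figure D2:**
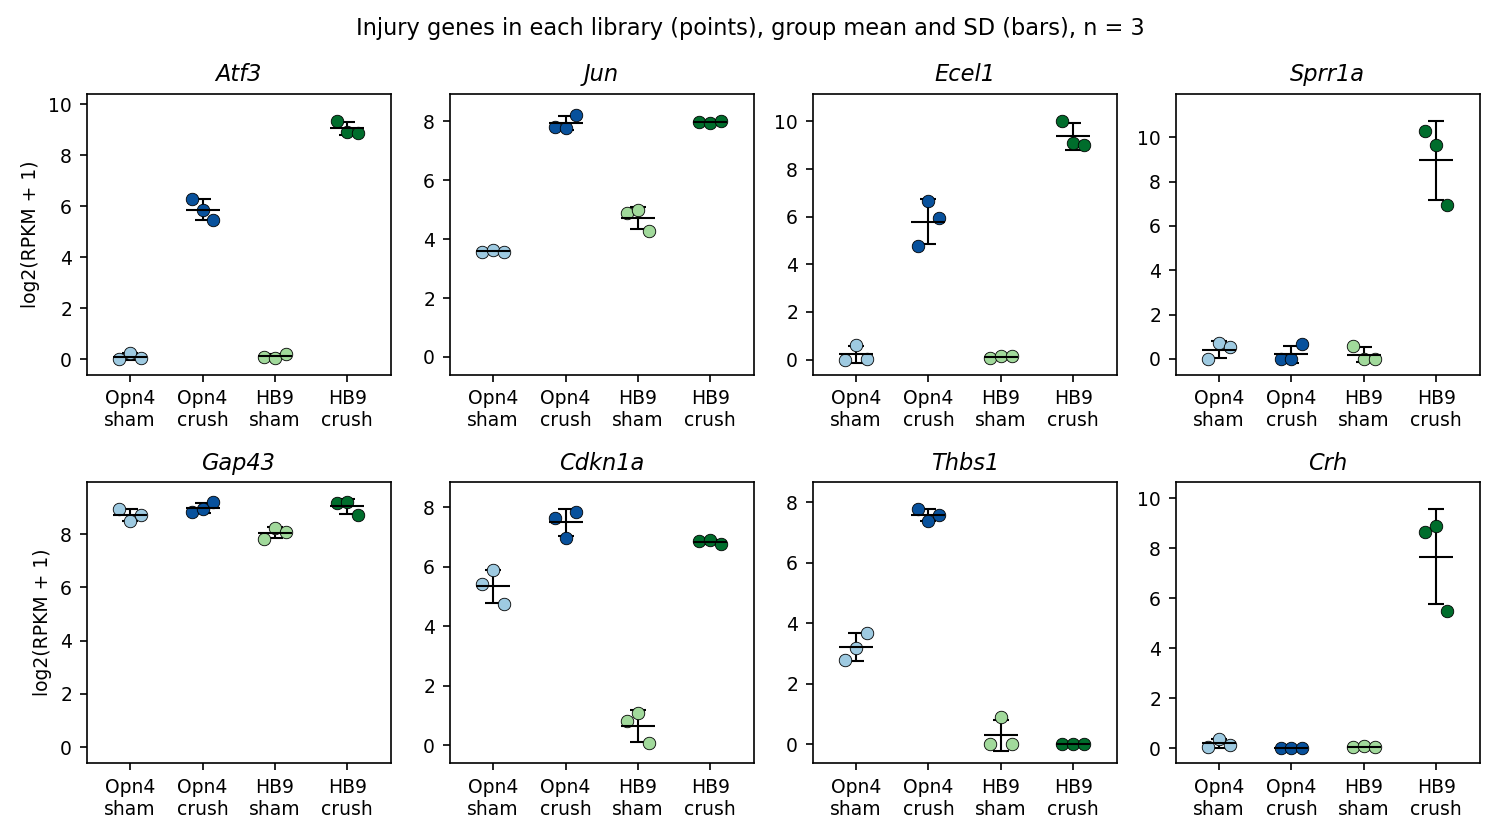
Level of 8 injury genes, as log2(RPKM + 1) on the vertical axis, in each library (points) of the 4 groups on the horizontal axis; bars give the group mean and SD (n = 3). Atf3 and Ecel1 rise in both classes, Sprr1a and Crh reach 729 and 305 RPKM in HB9 crush libraries, and Thbs1 reaches 192 RPKM in Opn4 crush libraries.

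The mean of both crush effects was tested for changes over both classes. Atf3 rose by 7.35 ± 0.22 (adjusted p = 1.61e-09), Ecel1 by 7.42 ± 0.32 (adjusted p = 5.40e-08) and Jun by 3.8 ± 0.15 (adjusted p = 2.20e-08). Cox6a2 (5.32), Mir147 (5.07), the actin regulator Avil (4.51), Tnfrsf12a (4.46), the serine synthesis enzyme Phgdh (4.31), AA467197 (4.27) and Arid5a (4.18) rose in both classes without overlap of libraries. Mir147 lies in AA467197, so these may not be separate changes. Osteopontin (Spp1), a secreted protein of alpha ganglion cells, rose by 4.81 ± 1.16 (adjusted p = 0.026), but not without HB9 crush 1, 2 or 3 (adjusted p up to 0.0608). Among genes that fell were the glutathione transferase Gsta4 (-3.61), the adhesion molecule Jam2 (-2.96), the growth factor Gdf10 (-2.79), Fxyd7 (-2.65), the microtubule protein Tppp3 (-2.23) and the cadherin Cdh7 (-2.23). Ccdc74a (-2.35), Ccl17 (-2.31), Cpne9 (-2.21) and Susd2 (-2.18) completed the 10 lowest. The count was 754 genes up and 521 down, 144 and 26 beyond 4-fold. Quantile normalization gave 664 up and 584 down, and median-ratio rescaling 692 and 652. Single-class calls overlapped: 73 genes rose in both classes where independent calls would give 4.84, and 26 fell in both against 1.98. Only Rgs4, a regulator of G protein signalling, was called up in Opn4 cells (1.1) and down in HB9 cells (-1.29), and Csdc2 and Siah3 were called the other way; these 3 were named after their values were seen. Across all tested genes, which are not independent replicates, the effects correlated at r = 0.218. Without HB9 sham 2, HB9 crush 1 or HB9 crush 3 the count of the mean effect was 803, 799 or 835.

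Lists were also tested on the mean of both crush effects. With either correlation, regeneration-associated genes (18 of 27 up, 1 down; 23 and 1 adjusted over the list alone; median 1.48, adjusted p = 0.000146 with an estimated correlation) and the stress response (18 of 27, 21 adjusted over the list alone; median 1.37, 0.000512) rose. Cholesterol synthesis (12 of 19, 14 adjusted over the list alone; median -1.01, 0.00556), voltage-gated channels (6 of 27, with 8 down and 1 up adjusted over the list alone; median -0.52, 0.0141) and ganglion cell genes (5 of 20, 10 adjusted over the list alone; median -0.43, 0.0266) fell. With the preset correlation alone, tubulins (median -0.52, adjusted p = 0.0596 with an estimated correlation), glycolysis (-0.29, 0.14), nuclear oxidative phosphorylation genes (-0.17, 0.429) and ooDSGC markers (-0.56, 0.0708) fell. Immediate early genes (0.56, 0.16), interferon-stimulated genes (0.96, 0.229), DLK-JNK and apoptosis genes (0.27, 0.16) and ribosomal proteins (0.17, 0.643) rose. So did cytokine signalling genes (0.49, 0.14) and Muller glia markers (1.11, 0.29). The call of cytokine genes ended without any library but Opn4 sham 1, Opn4 sham 2, Opn4 crush 3, HB9 sham 3 and HB9 crush 3 (adjusted p up to 0.0967). That of Muller glia markers ended without Opn4 sham 2 or 3, Opn4 crush 1, HB9 sham 3 or HB9 crush 1 or 2 (adjusted p up to 0.179), and that of ribosomal proteins without Opn4 sham 2, Opn4 crush 2 or HB9 sham 3 (adjusted p up to 0.215). A mean effect can rest on 1 class. In Opn4 cells alone, ganglion cell genes and ooDSGC markers (adjusted p = 0.649 and 0.649), voltage-gated channels (0.229), glycolysis (0.13) and ribosomal proteins (0.743) did not pass, and cytokine genes and Muller glia markers passed in neither class alone.

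**Figure D3:**
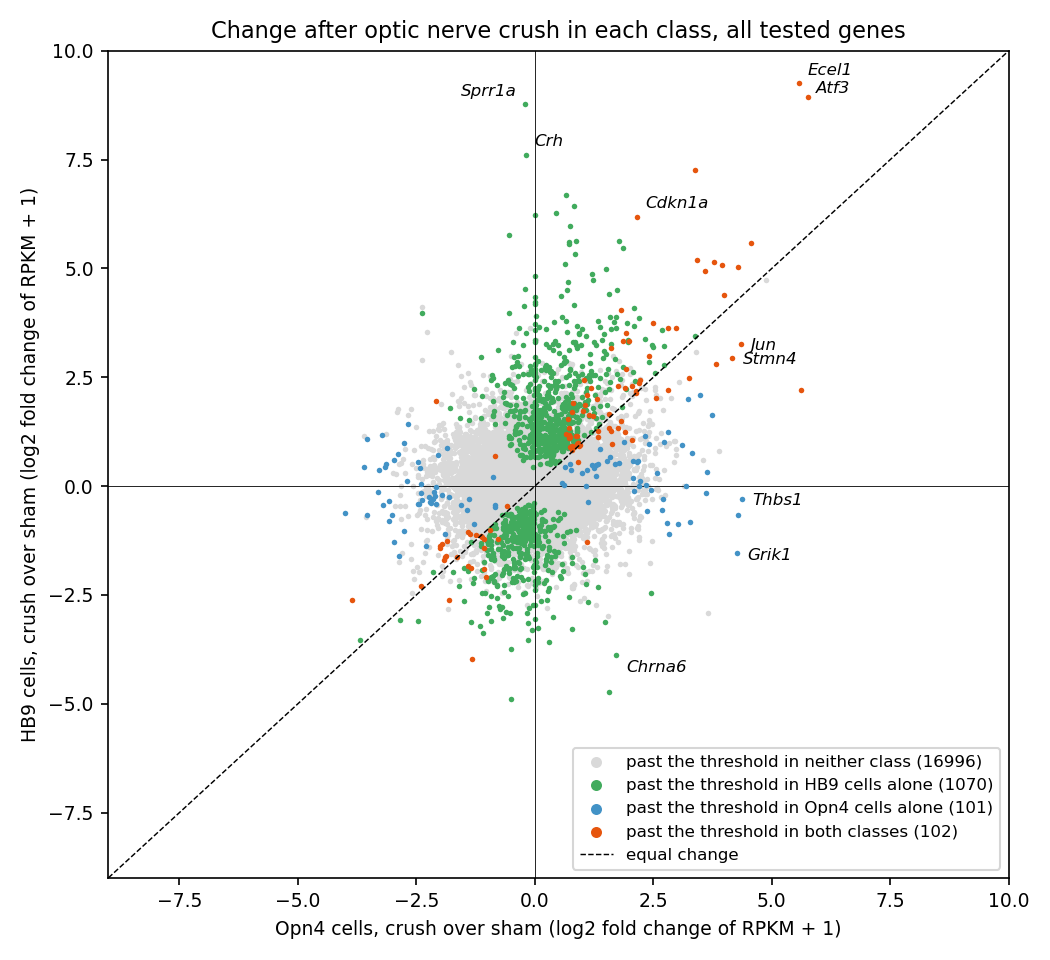
Log2 change after crush in Opn4 cells (horizontal axis) against HB9 cells (vertical axis), each point 1 of 18269 genes; colours mark genes past the threshold in both classes (102), in HB9 cells alone (1070), in Opn4 cells alone (101) or in neither (16996), and the dashed line marks equal change. Atf3 and Ecel1 lie above the line, Thbs1 and Jun below it.

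The difference of the crush effects, Opn4 minus HB9, tested which responses depend on class. Sprr1a, Crh and Ucn rose in HB9 cells and had group means of at most 0.195 RPKM in injured Opn4 cells. Their differences were -8.98 ± 0.99 (adjusted p = 0.00263), -7.8 ± 1.01 (adjusted p = 0.0050) and -6.23 ± 0.85 (adjusted p = 0.00679). Ecel1 and Atf3 rose in both classes but less in Opn4 cells, with differences of -3.68 ± 0.65 (adjusted p = 0.0207) and -3.18 ± 0.44 (adjusted p = 0.00742). Thbs1 went the other way, rising in Opn4 cells alone, with a difference of 4.66 ± 0.57 (adjusted p = 0.00434). Chrna6, which fell in HB9 cells, differed by 5.6 ± 0.80 (adjusted p = 0.00763), and the synaptic pentraxin Nptx2 by 3.89 ± 0.61 (adjusted p = 0.0127). The difference passed for 149 genes, 53 higher and 96 lower in Opn4 cells, of which 31 and 74 differed by more than 4-fold, while 2351 had an unadjusted p under 0.05. Jun, at 1.08 (adjusted p = 0.131), Gap43, at -0.71 (adjusted p = 0.253), Sox11, at -1.25 (adjusted p = 0.628), and Rbpms, at 0.44 (adjusted p = 0.454), did not differ past the threshold. The median over all genes was -0.13, quantile normalization moved it by 0.13 and gave 78 genes higher and 93 lower, and median-ratio rescaling moved it by 0.10 and gave 76 and 86. Without HB9 sham 2 or HB9 crush 1 or 2 (adjusted p up to 0.0722) the call of Ecel1 ended. With voom, adjusted p was 0.467 for Sprr1a, 0.409 for Crh, 0.152 for Ucn, 0.611 for Atf3 and 0.233 for Thbs1. With a pseudocount of 0.1 it was 0.107 for Atf3, 0.153 for Ecel1, 0.0727 for Thbs1 and 0.065 for Chrna6. The count was 90, 61 or 78 without HB9 sham replicate 1, 2 or 3, 81, 90 or 81 without HB9 crush replicate 1, 2 or 3, and 93 without Opn4 sham replicate 3. It was 98 with the replicate block and 90 with a pseudocount of 0.1.

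The difference of the crush effects passed for 14 of 31 lists with the preset correlation and for 5 with an estimated one. The stress response rose more in HB9 cells, with 7 of 27 genes past the threshold (12 adjusted over the list alone). The median was -1.46 (adjusted p = 7.32e-13, and 0.00426 with an estimated correlation). Wars differed by -2.04 ± 0.20 (adjusted p = 0.00191), with changes of -0.44 in Opn4 cells and 1.6 in HB9 cells, and the chaperone Hspa5 by -1.51 ± 0.24 (adjusted p = 0.0135). Regeneration-associated genes also rose more in HB9 cells, with 6 lower and 1 higher in Opn4 cells of 27 (12 and 2 adjusted over the list alone). Their median was -1.09 (adjusted p = 6.69e-07, and 0.00706 with an estimated correlation). The list test of the difference also passed with either correlation for 3 lists that fell in HB9 cells and did not pass in Opn4 cells. These were synaptic release genes (1 of 24, 3 adjusted over the list alone; median 0.46, adjusted p = 0.00923 with an estimated correlation), ganglion cell genes (3 of 20, also 3 adjusted over the list alone; median 0.63, 0.0161) and voltage-gated channels (2 of 27, with 7 higher and 1 lower adjusted over the list alone; median 0.68, 0.0166). Cholesterol synthesis, which fell in both, had a median difference of 0.13 (adjusted p = 0.0953), and tubulins 0.02 (0.739, with a mean of -0.02). Rod markers did not differ in their crush effect (median -0.07, adjusted p = 0.805).

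**Figure D4:**
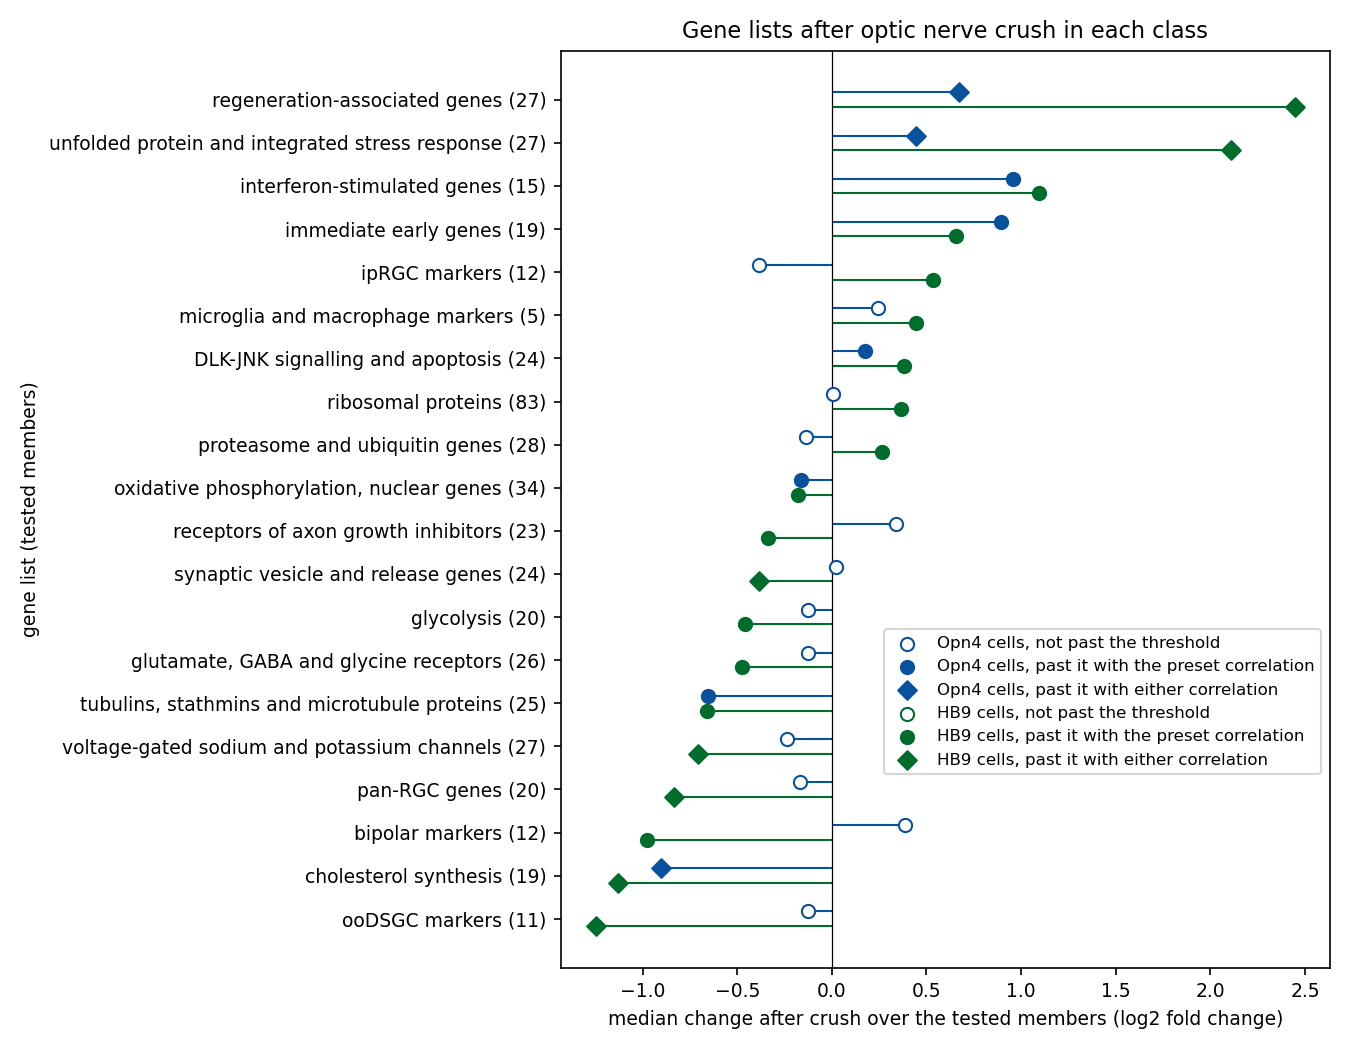
Median log2 change after crush (horizontal axis) over the tested members of the 20 lists past the threshold in either class (vertical axis, with the number of tested members), in Opn4 cells (blue) and HB9 cells (green); open symbols did not pass, circles passed with the preset correlation and diamonds with either correlation. The stress response list is at 0.45 in Opn4 cells and 2.11 in HB9 cells, and cholesterol synthesis at -0.90 and -1.13.

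The injured classes were compared to see how the cells differ once both have been lesioned. Thbs1 was at 192 ± 26.9 RPKM in Opn4 cells and 0.00415 ± 0.00718 in HB9 cells (7.58 ± 0.41, adjusted p = 1.52e-06), and Cd24a still set Opn4 cells apart (9.35 ± 0.52, adjusted p = 1.52e-06), as did Opn4 itself (6.9 ± 0.90, adjusted p = 0.000345). Lower in Opn4 cells were Sprr1a at -8.74 ± 0.70 (adjusted p = 9.58e-06), Atf3 at -3.19 ± 0.31 (adjusted p = 4.44e-05) and Crh at -7.67 ± 0.71 (adjusted p = 2.62e-05). Higher in Opn4 cells were also Gldn (7.24), the natriuretic peptide Nppb (6.8), the collagen Col9a1 (6.59), the growth factor Bmp7 (6.18), the transcription factor Tbx20 (5.84), Gna14 (5.78) and the sphingosine phosphate receptor S1pr3 (5.73). Also lower were Anxa2 (-6.25), Ucn (-6.23), Tfap2d (-6.22), Crhbp (-6.13), Pvalb (-6.11), the protease Prss12 (-5.99), the muscle protein Csrp3 (-5.86) and Anxa3 (-5.76, at least 1942-fold lower). The calls of Sprr1a and Crh ended with voom (adjusted p = 0.095 and 0.0626). In total 936 genes were higher and 1389 lower in Opn4 cells, 396 and 517 by more than 4-fold, with a median over all genes of -0.12 that quantile normalization moved by 0.11. The imbalance shrank with the scaling, to 1160 higher and 1185 lower with quantile normalization and 1042 and 1214 with median-ratio rescaling. Mnx1 still differed, at -1.7 ± 0.43 (adjusted p = 0.0201), a call that ended without HB9 crush 1 or 3 (adjusted p up to 0.0831). The count was 1356 without HB9 crush replicate 1, 1391 without replicate 3 and 870 with the rod covariate.

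After crush, 11 of 12 ipRGC markers were higher in Opn4 cells (12 adjusted over the list alone). The median was 4.79 (adjusted p = 5.05e-20, and 0.0031 with an estimated correlation). The stress response was lower in 14 of 27 and higher in 1 (17 and 2 adjusted over the list alone), with Asns at -2.23 and Chac1, which degrades glutathione, at -3.01. The median was -1.4 (adjusted p = 2.12e-08, and 0.010 with an estimated correlation). Before injury the same list had a median of 0.09, with a mean of -0.06 (adjusted p = 0.961). Cholesterol synthesis was higher in 10 of 19 (12 adjusted over the list alone). The list median was 1.02 (adjusted p = 1.43e-07, and 0.0389 with an estimated correlation). Thrombospondins and their receptors were higher in 6 of 14 (7 higher and 1 lower adjusted over the list alone). The median was 0.62 (adjusted p = 2.37e-05, and 0.0128 with an estimated correlation). With the preset correlation alone, glycolysis (median -0.82, adjusted p = 0.0737 with an estimated correlation), nuclear oxidative phosphorylation genes (-0.39, 0.398), proteasome genes (-0.33, 0.341) and ooDSGC markers (-2.17, 0.0611) were lower. Higher were bipolar markers (1.35, 0.315), tubulins (0.38, 0.341), immediate early genes (0.75, 0.341) and receptors of axon growth inhibitors (0.21, 0.315). The call of tubulins ended without HB9 crush 3 (adjusted p = 0.0625), that of immediate early genes without Opn4 crush 2 (adjusted p = 0.0521), and that of the receptors without Opn4 crush 1 or HB9 crush 2 (adjusted p up to 0.111). Rod markers were again higher, 2 of 15 (3 adjusted over the list alone). Their median was 1.27 (adjusted p = 8.24e-06, but 0.315 with an estimated correlation). With the rod covariate the call of bipolar markers ended (adjusted p = 0.114). Ganglion cell genes did not pass as a list (median -0.63, adjusted p = 0.0784), nor did synaptic release genes (-0.20, 0.168) or voltage-gated channels (-0.63, 0.0635), although many members differed. Of 20 ganglion cell genes 9 were lower and 3 higher (11 and 5 adjusted over the list alone), of 24 synaptic genes 8 and 3 (8 and 5), and of 27 channels 7 and 2 (10 and 2).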

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

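Genes and lists whose crush effects differ between the classes were picked out because the test of the difference between the crush effects of the classes (Opn4 minus HB9, limma) passed the threshold. Rod transcripts were not picked out by that test. The tests of rod carry-over, of ipRGC carry-over for Eomes and for Adcyap1, and of spread for the stress response list were chosen after the results were seen.

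Genes with a higher log2 change in Opn4 cells included Grik1 (5.8), Chrna6 (5.6), Thbs1 (4.66), Nptx2 (3.89) and Neurod2 (3.33). These kept their calls without any single library. Neurod2 was low throughout, with group means of at most 4.24 RPKM. The calls of Thbs1 and Chrna6 ended with a pseudocount of 0.1, and that of Thbs1 also with voom, as given above. Other calls ended, namely those of Scgn (6.31) without any library but Opn4 sham 1 and Opn4 crush 3 (adjusted p up to 0.133) and Mir5117 (4.94) without any library but Opn4 crush 2, HB9 sham 1, HB9 sham 3 and HB9 crush 2 (adjusted p up to 0.0806). So did those of Chrnb3 (4.92) without any library but Opn4 sham 1, Opn4 sham 2, Opn4 crush 2, Opn4 crush 3 and HB9 sham 1 (adjusted p up to 0.0779) and Mmp9 (4.59) without any library but Opn4 sham 3 and Opn4 crush 1 (adjusted p up to 0.0959). The same held for Kctd4 (3.89) without any library but Opn4 crush 1, Opn4 crush 2, HB9 sham 2 and HB9 crush 2 (adjusted p up to 0.0919) and Mnx1 (3.24) without Opn4 sham 3, HB9 sham 2 or 3 or HB9 crush 1, 2 or 3 (adjusted p up to 0.0849). Among neuronal genes it held for Nrn1 (1.24) without any library but Opn4 sham 3, Opn4 crush 1, Opn4 crush 2 and Opn4 crush 3 (adjusted p up to 0.083) and Ptprs (1.48) without any library but Opn4 sham 1, Opn4 sham 3, Opn4 crush 2, HB9 sham 1 and HB9 crush 3 (adjusted p up to 0.0849). Among channel genes it held for Kcnc1 (2.0) without any library but Opn4 sham 1, Opn4 sham 2, Opn4 crush 1 and Opn4 crush 2 (adjusted p up to 0.0947) and Kcnab2 (1.3) without any library but Opn4 sham 1, Opn4 sham 2, Opn4 crush 1, Opn4 crush 2 and HB9 crush 1 (adjusted p up to 0.0905). Among synaptic genes it held for Rab3a (1.07) without Opn4 sham 3, HB9 sham 1 or 2 or HB9 crush 1 or 3 (adjusted p up to 0.0779) and Grin1 (1.78) without HB9 sham 2 (adjusted p = 0.0625). Grik1 and Scgn are also on the list of bipolar markers.

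Genes with a lower log2 change in Opn4 cells included Sprr1a (-8.98), Crh (-7.8), Prss12 (-6.33), Ucn (-6.23), Crabp2 (-5.81), Gpnmb (-5.62), Zcchc12 (-5.23) and Cdsn (-4.82, at least 2087-fold lower in Opn4 cells after crush). They also included Cdkn1a (-4.04), Atf3 (-3.18), Eomes (-3.11), Adcyap1 (-2.55), Slc3a2 (-2.51), Slc7a5 (-2.21), Wars (-2.04) and Hspa5 (-1.51). The call ended for Sstr2 (-6.35) without any library but Opn4 sham 3, Opn4 crush 2 and HB9 crush 1 (adjusted p up to 0.0953) and for Cd68 (-6.04) without any library but Opn4 crush 1 (adjusted p up to 0.0966). It also ended for Ecel1 (-3.68) without HB9 sham 2 or HB9 crush 1 or 2 (adjusted p up to 0.0722) and for Sqstm1 (-0.84) without any library but Opn4 sham 2 (adjusted p up to 0.102).

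Lists whose median difference was positive were bipolar markers (1.55, adjusted p = 0.272 with an estimated correlation), ooDSGC markers (0.87, 0.0647), voltage-gated channels (0.68, 0.0166), ganglion cell genes (0.63, 0.0161), synaptic release genes (0.46, 0.00923) and markers of other ganglion cell types (0.44, 0.0708). Receptors of axon growth inhibitors (0.40, 0.167), transmitter receptors (0.30, 0.384) and glycolysis (0.26, 0.272) were also positive. Negative were the stress response (-1.46, 0.00426), ipRGC markers (-1.21, 0.0708), regeneration-associated genes (-1.09, 0.00706), proteasome and ubiquitin genes (-0.48, 0.272) and ribosomal proteins (-0.37, 0.758). The preset call ended for other ganglion cell types without Opn4 sham 3 (adjusted p = 0.0651), for transmitter receptors without Opn4 sham 1, Opn4 crush 2, HB9 sham 2 or HB9 crush 1 (adjusted p up to 0.16) and for ribosomal proteins without Opn4 sham 1, Opn4 crush 1 or HB9 sham 3 (adjusted p up to 0.099).

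Changes after crush were larger in HB9 cells: over the 1275 genes past the threshold for the mean effect, the median change in its direction was 0.70 in Opn4 cells and 1.23 in HB9 cells. A share of cells without a response, alike in every Opn4 crush pool, would lower all increases by 1 factor, and it cannot be told apart from a weaker response. Of 73 genes called up in both classes, 9 (12.3%) had a larger RPKM increase in Opn4 cells beyond the library ranges, past the bound of 1 in 10 set before. That bound was wrong, because it took the increases of a gene without dilution to be alike in both classes, and Dusp1, 1 of the 9, already differed after sham (95.9 against 28.8 RPKM). Changes of like size hidden by the larger spread of the Opn4 libraries cannot be told apart from smaller changes for these genes as a set, since the ratio of the medians was 0.566 and ran from 0.5 to 0.676 without single libraries, past the bound of 0.67 set before. For the stress response list, fixed in advance but picked out because its difference passed, the tables argue against hidden changes of like size. Its median difference was -1.46 (-1.57 to -1.18 without single libraries), and 26 of 27 members were negative. The list mean rose by at most 0.987 between any Opn4 sham and crush library and by at least 1.83 between any HB9 ones. A biological difference between the classes stays open, as does the Cre recombinase of the Opn4 line.

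Rod transcripts were higher in the Opn4 libraries, with 0.224% to 0.4% of recovered reads after sham and 0.267% to 0.592% after crush, against 0.107% to 0.143% and 0.0929% to 0.169% in HB9 libraries. Rod RNA carried over from the retina is a candidate source: within groups the 15 rod genes moved together, with a mean correlation of 0.566 against 0.0982 at the 95th percentile of 1000 matched random lists. As the cause of the lower ganglion cell genes in uninjured Opn4 cells the tables argue against it, because with the mean rod value as a covariate their median difference was -1.03, from -1.33 without it (adjusted p = 1.25e-06; quartiles -2.46 to 0.23). Whether rod RNA entered in the dissociation or the picking was not tested. No biological explanation of rod transcripts in these pools was tested.

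The ipRGC markers Eomes and Adcyap1 rose after crush in HB9 cells, by 3.23% and 35.1% of their level in injured Opn4 cells. Stray ipRGCs or their RNA would bring the other abundant ipRGC markers in like shares. For Adcyap1 the tables argue against this, since the median share of the other 9 markers was at most 1.69% even from the highest crush and the lowest sham library. From group means, Baiap3 at 11%, Igf1 at 4.05% and Trpc6 at 2.64% rose by shares near or above that of Eomes. Opn4 itself was at 0.502%, Nmb at 0.129%, Gna14 at 0.0714%, Tbx20 at -0.012%, Trpc7 at -0.0509% and Rasgrp1 at -1.29%. Stray ipRGCs would have brought these 6 as well. The highest rise of each of the 6 stayed below 2.36%, the lowest rise of Eomes between single libraries. However, the median of at most 1.69% is not far enough below the 3.23% of Eomes to meet the bound used for Adcyap1. Baiap3, Igf1 and Trpc6 also go the other way. For Eomes the values argue only against ipRGCs that bring all markers alike, and stray RNA is not excluded. Adcyap1 is also on the list of regeneration-associated genes, fixed in advance, and was already at 42.1 RPKM in HB9 cells after sham. A biological rise of Eomes and Adcyap1 in ooDSGCs is a hypothesis, found and tested on the same libraries.

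With 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. In Opn4 cells the crush comparison gave 203 genes, at most 12 in the other splits, and 1 of the 10 splits gave as many, the real one. In HB9 cells it gave 1172, with at most 1 in the others, so 1 of 10. After sham the class comparison gave 2148, at most 1 in the others, and after crush 2325, at most 2, each again 1 of 10. For the mean effect 100 of 200 splits were used, the real one among them by choice. Only the real one gave 1275 genes, a share under 0.05. The highest other, at 448, kept HB9 sham and crush apart and mixed the Opn4 groups, and the 76 splits that mix both classes gave at most 2. The count thus carries the HB9 crush effect and does not by itself show a change in both classes. For the difference, 8 of 100 drawn splits gave at least the 149 genes of the real split, so chance is not excluded for that count by these splits. They do not measure chance alone, since besides the real split the highest, 1275, swaps sham and crush in 1 class and so tests the mean effect. The other 6 mix the Opn4 groups but keep HB9 sham and crush apart, up to 374 genes, and so carry the HB9 crush effect. The 82 splits that mix both classes gave at most 2 genes.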

How the results depend on the processing

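Limma voom on recovered reads, the rod covariate, named protein-coding genes and the fit without the 2 Opn4 libraries that stood apart were tests chosen after the results were seen. Over all alternatives, 0 of the named gene results and, apart from the rod list, 0 list results reversed. Of 494 named gene calls, the replicate block ended 30, a pseudocount of 0.1 ended 38, no filter 72, quantile normalization 19, median-ratio rescaling 6, voom 78 and the rod covariate 98. Of 85 list calls, an estimated correlation ended 54, which bears on list claims more than any other setting tried, and the replicate block 0. Left out, a library makes its group rest on 2 libraries, and the cause of lower counts is in part that smaller number. Depth limits genes near 0 RPKM, whose log2 changes shrink with the pseudocount.

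With a threshold of 0.1 the count was 460 for the Opn4 crush effect, 1942 for the mean and 310 for the difference, as a looser threshold must give. With weighted libraries it was 87 in Opn4 and 3025 in HB9 cells, with weights from 0.424 (Opn4 sham 1) to 2.73 (HB9 sham 2). Fitted on the groups compared alone it was 13 in Opn4 and 1939 in HB9 cells, where each class keeps its own spread and fewer libraries. The difference gave 90 genes with a pseudocount of 0.1 and 98 with the replicate block; the cause was not tested. The rod covariate left 784 genes after sham and 870 after crush between classes and turned the rod list to -0.24 and -0.21, as its construction implies. Without single libraries the counts ran from 148 to 224 for Opn4 crush, 645 to 777 for HB9 crush, 799 to 1218 for the mean, 61 to 156 for the difference, 1348 to 1923 between classes after sham and 1356 to 2201 after crush. Without the 2 Opn4 libraries that stood apart the Opn4 crush count was 161, of which 92 were among the 203.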

Other observations

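Members of several growth and signalling lists that did not pass changed after crush in HB9 cells. Of the Kruppel-like factors, Klf6, which promotes axon growth, rose by 1.72 ± 0.21 (adjusted p = 0.000397), and the list did not pass (median 0.38, adjusted p = 0.0806). Stat3, the signal transducer of the gp130 cytokines, rose by 1.62 ± 0.30 (adjusted p = 0.00574), and the cytokine list did not pass (0.37, 0.101). Eif4ebp1, a translational repressor under mTOR control, rose by 5.55 ± 0.89 (adjusted p = 0.00216) and the mTOR activator Rheb by 0.98 ± 0.17 (adjusted p = 0.00359), with the mTOR list at 0.09 (0.358). In Opn4 cells the insulin receptor substrate Irs2 rose by 1.77 ± 0.28 (adjusted p = 0.00806), though not without the libraries that stood apart (adjusted p = 0.0545). The syndecan Sdc2 rose in HB9 cells by 2.01 ± 0.31 (adjusted p = 0.00169), and the thrombospondin list had a median of -0.01 and a mean of 0.23 (0.61). Cytosolic chaperones Hsp90aa1 (1.08 ± 0.14, adjusted p = 0.000471) and Hspb1 (2.62 ± 0.43, adjusted p = 0.00266) rose there as well, with the heat shock list at 0.19 (0.113). Of 23 neuropeptides and secreted factors, 7 rose and 4 fell in HB9 cells (10 and 6 adjusted over the list alone; list adjusted p = 0.215), chromogranin A (Chga) at -1.04 ± 0.13 (adjusted p = 0.000354). After crush in HB9 cells cone markers (0.50, 0.812), amacrine markers (0.99, 0.113), Muller glia markers (1.25, 0.119) and rod markers (0.60, 0.298) did not pass.

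The test of the following hypothesis was set before its result was seen. Uninjured Opn4 cells may already hold part of the crush response of HB9 cells. Across genes, the covariance of the HB9 crush effect with the class difference after sham was 0.276, of which 0.0986 arises in 100 simulations from the shared HB9 sham libraries. The remainder was 0.177, from 0.155 to 0.217 without single libraries, and above 0 each time. The correlation of the same values was 0.319, against 0.50 in the simulations, where no gene truly changed. Genes higher in HB9 cells that fall after crush, Chrna6 and Mnx1 among them, add to the covariance as well. The covariance does not separate these, so the remainder does not by itself show the hypothesis. Of 702 genes called up after crush in HB9 cells, 156 were called higher in uninjured Opn4 cells, where independent calls would give 40.9. Another 44 were called lower, against 41.7. Both calls use the same HB9 sham libraries, whose noise raises the first overlap, so these counts do not show the hypothesis either. Genes are not independent replicates, and the Cre recombinase and rod RNA of the Opn4 pools stay open as sources of the excess.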
